A study of Homo sapiens with 20 samples.

How the data were processed

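RNA sequencing was done on peripheral blood mononuclear cells (PBMC), separated on a density gradient from the blood of 7 patients with Lyme disease. Total RNA was extracted with TRIzol, polyadenylated RNA was selected, and libraries were made with the ScriptSeq kit and read from both ends, as the labels state. The deposited values are FPKM (fragments per kilobase of gene, scaled to the number of mapped fragments of the library), which the authors estimated for each library alone with Cufflinks after alignment with TopHat2 and Bowtie2 2.2.2 to hg19, per the submitters' processing notes. The versions of TopHat2 and Cufflinks and the gene annotation used are not given in the sources used here. Each file lists 25278 gene entries with FPKM, its confidence bounds and a quantification status, and every entry has the status OK.

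Entries were joined by gene symbol, which gave 23615 symbols. FPKM was summed for the 554 symbols that had more than 1 entry. Coordinates are those of the deposited files (hg19, counted from 1). The files hold no read counts, so that sequencing depth is unknown and no counting interval was computed. As a measure of precision, the width of each confidence bound was taken as 2 SD of FPKM, and the number of fragments that would give that SD by counting alone was summed over genes. This effective fragment number was 439266 to 2241568 per library and is a measure of relative precision, not a depth.

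Genes with a mean FPKM of at least 1 over the 20 libraries were tested (10919 genes). Small RNA genes (1719 symbols), whose FPKM can be unstable for short transcripts, and genes of the Y chromosome and XIST were left out of the tests. Values were transformed as log2(FPKM + 1), with no further scaling between libraries. Differences between visits were estimated with limma 3.58.1 in R 4.3.3, with statmod 1.5.0, in 1 fit of all 20 libraries with patient as a fixed block and visit as the factor. The fit used empirical Bayes moderation with a trend on mean expression and had 11 residual degrees of freedom. The 3 visits were compared in pairs, and an F test asked for any difference among them. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05.

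Before the data were examined, 33 gene lists (18 pathway lists and 15 lists of cell type markers) were written down, as were the comparisons, the threshold, the rule for named genes and the alternative settings. Each list was tested with limma's camera with a preset correlation between genes of 0.01, which compares a list with all other tested genes, and again with the correlation estimated from the data. Limma's fry, which tests whether the genes of a list move on balance in 1 direction, was run beside it. Members were also tested within their list, given as "adjusted over the list alone". The level of a list is the mean log2(FPKM + 1) of its members in a library. Differences of levels within patients were tested with a two-sided exact permutation test that flips the signs of the differences, whose smallest possible p is 0.0312 with 6 patients and 0.0156 with 7. List tests were adjusted over the 33 lists of a comparison.

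The rule for named genes took, in each comparison, up to 8 genes per direction with the largest change among called genes that moved the same way in every patient. Where none passed, it took the 3 genes with the lowest p in each direction. From each of up to 6 lists with the lowest camera p it took the 3 members with the lowest p, and in every comparison CD14, MS4A1, CD3E, NKG7, FCGR3B, HBB, PPBP, IFI44L, FOS and TNF. Not every gene that the rule took is given in the text. Genes of highly variable families and genes with common deletions were excluded from the rule. CCL3L1, which varies in copy number between people, falls outside it and was chosen after its values were seen.

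The pipeline was tested on simulated data with the means and spread of the 10919 genes, in which 100 genes were changed by 1 and 100 by 2 on the log2 scale. It recovered 49%, 40% and 44% of the smaller changes in end of treatment against pre-treatment, 6 months against pre-treatment and 6 months against end of treatment. For the larger changes it recovered 97%, 95% and 96%. It called 5, 5 and 9 unchanged genes in the 3 comparisons, and 0 genes when nothing was changed. The changed genes were picked at random, and the interferon-stimulated genes were lowered as well. Noise was drawn independently for each gene, so that genes that move together were not simulated. Recovery and false calls in the real data can therefore differ from these values.

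The alternative settings were a pseudocount of 0.1, no filter and a minimum mean FPKM of 5, quantile normalization, median-of-ratios scaling, scaling to a common total, no replicate block, patient as a random effect, a fit of only the 2 visits compared, library weights, robust moderation, keeping small RNA genes, ignoring the quantification status, fry and an estimated correlation for lists, and leaving out each patient in turn. Leaving out pre-treatment replicate 2, leaving out pre-treatment replicates 2 and 4, and a correction of each library for GC content (lowess, span 0.3) were added after the data were seen. GC content and transcript length came from the transcripts of GENCODE release 29, matched by symbol for 10112 of the tested genes (92.6%). Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.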

Results

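Expression was measured by RNA sequencing in PBMC, the lymphocytes and monocytes of blood, from 7 patients with Lyme disease, a tick-borne infection with Borrelia bacteria. Blood was taken before antibiotic treatment (pre-treatment, 7 libraries), 3 weeks later at the end of treatment (6 libraries) and 6 months after treatment (7 libraries). Replicates within a visit are libraries of separate patients, a replicate number stands for the same patient at every visit, and 6 patients had all 3 visits. No library came from a healthy person, so that each comparison is between visits. The comparisons ask how the PBMC transcriptome differed between infection, the end of antibiotics and the months in which symptoms can persist after treatment. Log2 changes are on the scale of log2(FPKM + 1) with their SE from limma, and list levels are given with the SD between patients.

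The files used give FPKM and no read counts, so that the depth of each library is unknown. The effective fragment number derived from the deposited confidence bounds ranged from 439266 to 2241568, with a median of 963145 over the 20 libraries. Its mean was 1045192 ± 507056 (SD, n = 7) at pre-treatment, 1120699 ± 449021 (n = 6) at the end of treatment and 1074607 ± 532343 (n = 7) at 6 months. The number of genes with at least 1 FPKM was 10266 to 11042 in 19 libraries and 8572 in pre-treatment replicate 2. That library had a median Spearman correlation across genes of 0.669 with the other libraries, where the others had 0.855 to 0.917. Its most abundant gene held 9.58% of the FPKM outside small RNA genes, against 1.46% to 3.24% in the others. The within-patient correlation estimated by limma was 0.0044, so that libraries of the same patient were on average hardly more alike than those of different patients.

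**Figure D1:**
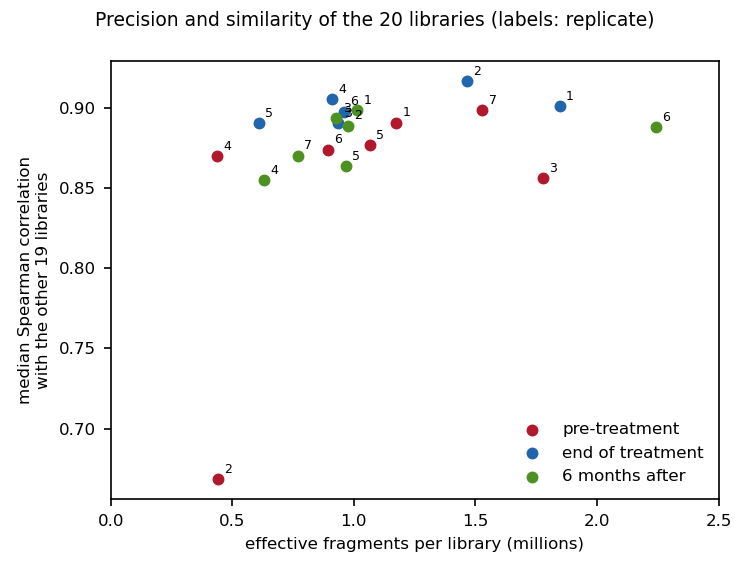
The x axis gives the effective fragment number of each library and the y axis its median Spearman correlation across genes with the other libraries. Dots are libraries, coloured by visit and numbered by replicate. Pre-treatment replicate 2 lies at 0.669 and the other libraries between 0.855 and 0.917.

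The mean levels of both interferon response lists were lower at the end of treatment than before treatment. The interferon-gamma response list, genes induced by the main cytokine of activated T and NK cells, had a level lower by -1.37 ± 1.28 (log2, SD, n = 6 patients), and 21 of its 26 measured members fell, adjusted over the list alone. Of the 35 interferon-stimulated genes, the antiviral program shared by all interferons, 17 fell, adjusted over the list alone, and the level differed by -0.94 ± 0.94. Over all genes tested, 0 members of either list passed. Levels at pre-treatment were spread widely between patients, from 3.13 to 6.10 for the interferon-gamma list (4.34 ± 1.28, SD, n = 7), and at the end of treatment they lay between 3.00 and 3.24 (3.15 ± 0.08, n = 6).

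Both interferon lists were called by camera (adjusted p = 8.9e-28 and 2.4e-27), and for both the adjusted p = 0.123 with an estimated correlation. In 6 months against pre-treatment that estimate was 0.648 for the interferon-gamma list and 0.435 for the interferon-stimulated list, against the preset 0.01. Camera p-values with the preset correlation are therefore too small for genes that move together. The level was lower in 5 of 6 patients for each, with exact permutation p = 0.0625 for the interferon-gamma list and 0.0938 for the interferon-stimulated list. In replicates 2, 3 and 4 the interferon-gamma level went from 5.12, 6.10 and 5.79 to 3.24, 3.12 and 3.19. In replicates 1, 5 and 6 it went from 3.49, 3.47 and 3.13 to 3.14, 3.00 and 3.175. The interferon-stimulated level of replicate 1, counted as lower, went from 2.84 to 2.79. ISG15 (chromosome 1, 948847 to 949919), a ubiquitin-like modifier, had a mean of 10.8 ± 2.99 FPKM (SD, n = 6) at the end of treatment and 82.6 ± 124 (n = 7) before it, a log2 change of -2.17 ± 0.45. Its pre-treatment mean rests largely on replicate 2, at 356.9 FPKM, where the others had 16.92 to 90. IFIT3, which binds into antiviral RNA sensing complexes, changed by -2.46 ± 0.55, and GBP1, a GTPase of cell-autonomous defence, by -2.16 ± 0.63. UBE2L6, the enzyme that passes ISG15 to its targets, changed by -1.22 ± 0.34, and each of these 4 genes was lower in 6 of 6 patients. CXCL10, a chemokine that attracts activated T cells, changed by -2.35 ± 0.60 and was lower in 5 of 6. IFI27 (chromosome 14, 94577079 to 94583033) had 7.81 ± 10.3 FPKM (n = 7) before treatment and was listed at 0 in 4 of 6 libraries at its end, so that its log2 change of -2.43 ± 0.45 was -4.92 with a pseudocount of 0.1.

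Inflammatory cytokine and NF-kB target genes were also lower at the end of treatment. The list level differed by -0.96 ± 0.59 (SD), lower in 6 of 6 patients with an exact permutation p = 0.0312, the smallest possible with 6, but adjusted over the 33 lists no exact test passed (smallest adjusted p = 0.644). Of the 30 measured members, 10 fell, adjusted over the list alone, 0 passed over all genes tested, and camera gave an adjusted p = 7.23e-17 (adjusted p = 0.178 with an estimated correlation). CCL3 (chromosome 17, 34415603 to 34417506), a chemokine for monocytes and T cells, had 141 ± 265 FPKM before and 4.18 ± 1.73 at the end of treatment, a log2 change of -3.95 ± 0.96. NFKBIA, the inhibitor that NF-kB induces against itself, changed by -1.97 ± 0.49, TNFAIP6, a hyaluronan-binding protein induced by TNF, by -1.82 ± 0.43, and TNF itself by -2.20 ± 0.79. CCL3, NFKBIA and TNF were each lower in 6 of 6 patients and TNFAIP6 in 5 of 6. The pre-treatment mean of CCL3 rests largely on replicate 6, at 739.6 FPKM, where the others had 20.3 to 83.8. TNF was 127.7 FPKM in that library and 4.64 to 16.6 in the others. Leaving out 1 patient or library at a time gave -4.28 to -3.48 for CCL3 and -2.68 to -1.74 for TNF.

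Some marker lists of other cell types were also called by camera with the preset correlation. Red cells and neutrophils are not among the lymphocytes and monocytes that make up PBMC. The source of their transcripts was not tested in any comparison. Of 13 measured erythroid markers, 7 fell, adjusted over the list alone (camera adjusted p = 1.99e-12, and adjusted p = 0.123 with an estimated correlation), with a level difference of -1.04 ± 0.77. The alpha-globin genes HBA2 and HBA1 changed by -2.19 ± 0.54 and -2.20 ± 0.55, HBB by -1.51 ± 0.47, and the red cell protein gene SELENBP1 by -1.04 ± 0.26. The B cell marker list rose by camera (adjusted p = 0.00118, and adjusted p = 0.411 with an estimated correlation). Its level was higher by 0.42 ± 0.53 in 4 of 6 patients, and by 0.27 without pre-treatment replicate 2, the library with the lowest correlation with the others. MS4A1, the B cell surface protein CD20, changed by 1.06 ± 0.36 (0.67 without replicate 2), and 0 of 18 members passed adjusted over the list alone. Mature neutrophil markers fell by camera (1 of 15 members, FFAR2 at -2.55, fell, adjusted over the list alone, adjusted p = 1.58e-05, and adjusted p = 0.417 with an estimated correlation), as did neutrophil granule genes (0 of 17, adjusted p = 0.00266, and adjusted p = 0.417 with an estimated correlation). Markers of T cells (adjusted p = 0.134), NK cells (0.266), classical monocytes (0.0895) and platelets (0.0895) were not called by camera, and CD3E, NKG7, CD14 and PPBP changed by 0.21, -0.15, -0.13 and 0.10.

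Of 73 nuclear genes of oxidative phosphorylation, the respiratory chain of mitochondria, 57 were below 0 and the list fell by camera (adjusted p = 1.71e-10, and adjusted p = 0.133 with an estimated correlation). Its mean log2 change was -0.23, 0 members passed adjusted over the list alone, and ATP5G1, COX7B and NDUFA11 changed by -1.09 ± 0.32, -0.56 ± 0.21 and -0.78 ± 0.31. NDUFA11 changed by -0.41 without replicate 2, whose pre-treatment library had 89.79 FPKM (others 12.2 to 21.3). Cell cycle genes fell by camera (adjusted p = 4.25e-07, and adjusted p = 0.347 with an estimated correlation), and 1 of 16 fell, adjusted over the list alone. This was TK1, a thymidine kinase of S phase, at -0.88 ± 0.23, beside UBE2C at -1.02 ± 0.44 and RRM2 at -0.84 ± 0.39, which did not pass. RRM2 was lower in 3 of 6 patients, with -0.53 without replicate 3 and -0.55 without replicate 5.

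In the comparison of the end of treatment with pre-treatment, limma called 0 of 10919 genes (smallest adjusted p = 0.214). At an unadjusted p under 0.05 there were 710 genes, 395 higher and 315 lower. Where 0.05 of the tested genes is 546, splits that swapped the 2 visits within patients gave a median of 536. The 3 genes with the lowest p that were lower were SLED1 (-1.42 ± 0.25), IFI27 (-2.43 ± 0.45) and the histone gene HIST2H2AA4 (-1.83 ± 0.35), and the 3 that were higher were ZNF586 (1.02 ± 0.23), ZNF383 (0.93 ± 0.23) and NAP1L5 (1.03 ± 0.26). All 6 moved the same way in 6 of 6 patients, and none passed (adjusted p from 0.214 to 0.36). IFI44L and FCGR3B, an interferon-stimulated gene and a neutrophil receptor gene, changed by -1.28 ± 0.40 and -0.98 ± 0.61 (FCGR3B -0.42 without replicate 3 and -1.65 without replicate 6), and FOS by 0.68 ± 0.62 (0.29 without replicate 6). The median log2 change of all genes was 0.13, which scaling to a common total moved to 0.36, median-of-ratios scaling to 0.01 and quantile normalization to 0.03, so that changes of single genes stand relative to it. Camera called 15 of the 33 lists, 1 higher and 14 lower, against 0 with an estimated correlation and 0 with fry. The call of the B cell list was lost without the replicate block (adjusted p = 0.123) and without replicate 3 (0.0674), that of the granule genes without the block (0.132), at a mean FPKM of at least 5 (0.0552) and without pre-treatment replicate 2 (0.0828), that of mature neutrophil markers without replicate 3 (0.0535), and that of cell cycle genes at a mean FPKM of at least 5 (0.0963). Without the replicate block 392 genes had an unadjusted p under 0.05, with only the 2 visits compared CCL3 was called (adjusted p = 0.0282), and the count of genes was 453 without replicate 4, 468 without pre-treatment replicate 2 and 1302 without replicate 5.

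**Figure D2:**
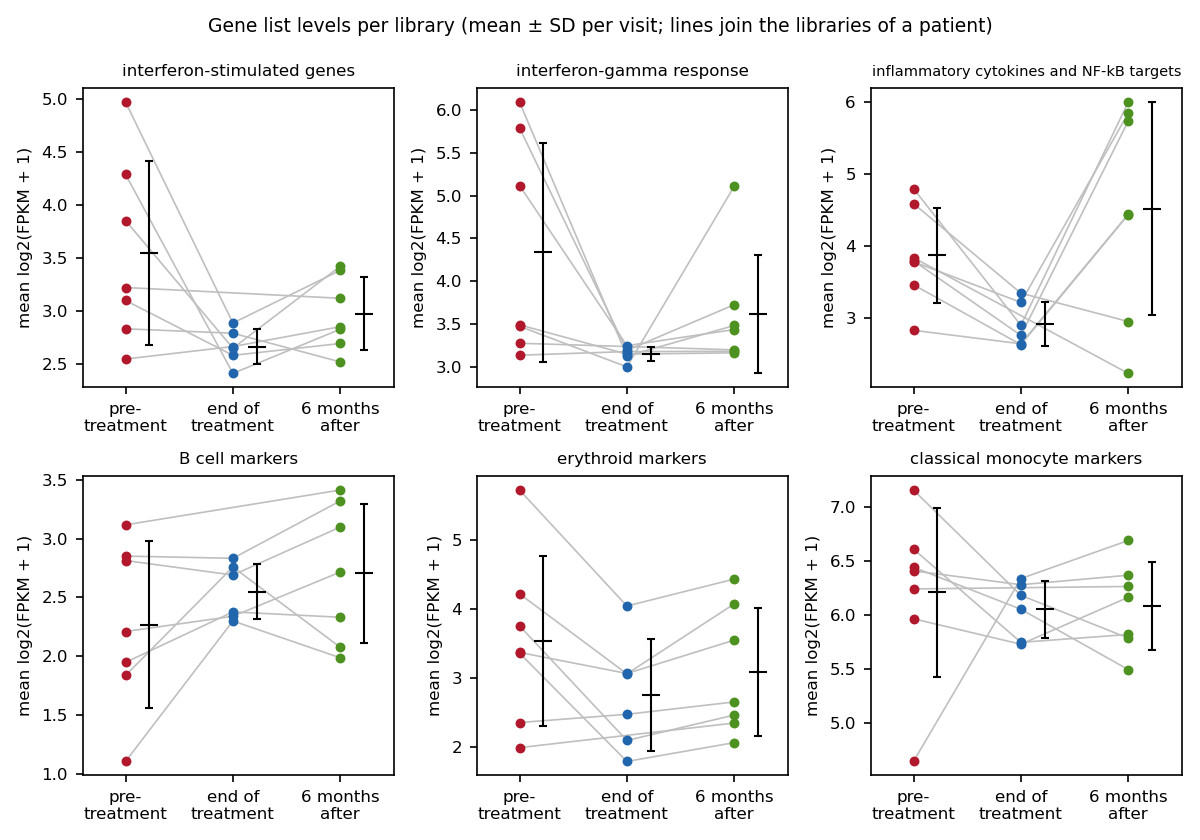
Each panel gives the level of 1 gene list (mean log2(FPKM + 1) of its members, y axis) at the 3 visits (x axis). Dots are libraries, grey lines join libraries of the same patient, and black marks are the mean ± SD. The interferon-gamma response list spans 3.13 to 6.10 before treatment and 3.00 to 3.24 at its end.

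At 6 months against pre-treatment, interferon lists fell and the B cell marker list rose by camera with the preset correlation, while 2 single genes of these lists passed, adjusted over the list alone. The level of the interferon-stimulated list differed by -0.57 ± 0.70 (SD, n = 7 patients), lower in 6 of 7 patients (exact permutation p = 0.0469), and 32 of 35 members were below 0. This test did not pass with quantile normalization (exact permutation p = 0.0625) or median-of-ratios scaling (0.0781). The list fell by camera (adjusted p = 8.19e-22, and adjusted p = 0.335 with an estimated correlation), and 1 member, IFI27, fell, adjusted over the list alone, with 0 over all genes tested. IFI27 was listed at 0 in 6 of 7 libraries at 6 months, and its log2 change of -2.30 ± 0.43 was in the same direction in 7 of 7 patients (adjusted p = 0.207). With a pseudocount of 0.1 it was -4.81, since the size of a change to values near 0 depends on the pseudocount. IFI44L changed by -1.15 ± 0.38 and IRF7, the transcription factor that amplifies the interferon response, by -0.79 ± 0.27 (-0.50 without replicate 2). The interferon-gamma response list also fell by camera (adjusted p = 3.04e-16, and adjusted p = 0.335 with an estimated correlation), but 0 of 26 members passed adjusted over the list alone. Its level differed by -0.73 ± 1.48 in the same direction in 5 of 7 patients, with -0.41 without replicate 3 and -1.12 without replicate 5. IDO1, an enzyme of tryptophan breakdown, changed by -1.03 ± 0.38 (lower in 4 of 7 patients, -0.66 without replicate 4), UBE2L6 by -0.75 ± 0.32 (lower in 5 of 7 patients, -0.47 without replicate 4 and -0.49 without replicate 3) and the immunoproteasome gene PSMB10 by -0.62 ± 0.27 (lower in 4 of 7, -0.36 without replicate 2).

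The B cell marker list was higher by 0.44 ± 0.22 in 7 of 7 patients (exact permutation p = 0.0156, the smallest possible with 7). Without pre-treatment replicate 2 it was higher by 0.36 ± 0.11 in 6 of 6 (exact permutation p = 0.0312). It rose by camera (adjusted p = 2.38e-06, and adjusted p = 0.335 with an estimated correlation), and of 18 members 1, TCL1A, a gene of naive B cells, rose, adjusted over the list alone (1.01 ± 0.29, limma p adjusted over the list = 0.0492, higher in 7 of 7). TCL1A was listed at 0 in pre-treatment replicate 2, and leaving out 1 patient or library at a time gave 0.70 to 1.14. FCRL1, a receptor-like protein of B cells, changed by 0.67 ± 0.27 and MS4A1 by 0.68 ± 0.34 (0.32 without replicate 2). Adjusted over the 33 lists, no exact test passed (smallest adjusted p = 0.515).

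NK cell markers rose by camera (0 of 19 members passed adjusted over the list alone, adjusted p = 1.73e-05, and adjusted p = 0.335 with an estimated correlation). Their level was higher by 0.43 ± 0.55 in 6 of 7 patients, and by 0.30 in 5 of 6 without pre-treatment replicate 2. The chemokine genes XCL2 and XCL1 changed by 1.33 ± 0.41 and 0.70 ± 0.24 and S1PR5, a receptor for egress from tissues, by 0.80 ± 0.28, while NKG7 changed by 0.16 ± 0.29. Both XCL2 and XCL1 were listed at 0 in pre-treatment replicate 2. Leaving out 1 patient or library at a time gave 0.97 to 1.71 for XCL2 and 0.49 to 0.80 for XCL1. Immediate early genes, the first genes transcribed after a stimulus, rose by camera (adjusted p = 2.1e-05, and adjusted p = 0.454 with an estimated correlation), a call that was lost without replicate 5 (adjusted p = 0.677). Their level was higher by 0.432 ± 0.823 (SD) in 4 of 7 patients (exact permutation p = 0.219). Of 26 members 1, JUN, a subunit of the transcription factor AP-1, rose, adjusted over the list alone (1.35 ± 0.34), and FOS changed by 0.01 ± 0.58. JUN was at 2.87 FPKM in pre-treatment replicate 2, and leaving out 1 patient or library at a time gave 0.98 to 1.62. The inflammatory cytokine list rose by camera (0 of 30 adjusted over the list alone, adjusted p = 0.000134, and adjusted p = 0.696 with an estimated correlation), a call lost without replicate 5 (adjusted p = 0.421) and without replicate 4 (0.0668). Its level was higher by 0.65 ± 1.60 in 5 of 7 patients, less than the spread between them, and by 0.415 in 4 of 6 without pre-treatment replicate 2. TNF changed by 0.99 ± 0.74, with 0.40 without replicate 2 and 1.87 without replicate 6.

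Erythroid markers fell by camera (adjusted p = 5.05e-06, and adjusted p = 0.335 with an estimated correlation). Their level differed by -0.455 ± 0.798 (SD), lower in 4 of 7 patients (exact permutation p = 0.234). Of 13 members 1, SELENBP1, fell, adjusted over the list alone (-0.82 ± 0.25, lower in 7 of 7). In replicate 6 SELENBP1 was near 0 at both visits (0.046 and 0.028 FPKM). HBA2, HBA1 and HBB changed by -1.29 ± 0.51, -1.25 ± 0.52 and -0.28 ± 0.45, and HBB was higher in 4 of 7 patients. Genes of oxidative phosphorylation fell by camera (0 of 73 adjusted over the list alone, adjusted p = 1.73e-05, and adjusted p = 0.4 with an estimated correlation), a call that was lost with quantile normalization (adjusted p = 0.0766). Their level differed by -0.109 ± 0.192 (SD), lower in 4 of 7 patients (exact permutation p = 0.156). Members went both ways, with ATP5G1 at -1.20 ± 0.30, NDUFB2 at -0.75 ± 0.28 and NDUFB6 at 0.82 ± 0.26. CD14, CD3E, FCGR3B and PPBP changed by -0.01, 0.31, -0.01 and 0.50, each by less than its SE.

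In the comparison of 6 months with pre-treatment, limma called 0 genes (smallest adjusted p = 0.111). An unadjusted p under 0.05 was found for 357 genes, 215 higher and 142 lower. Where 0.05 of the tested genes is 546, splits that swapped the 2 visits within patients gave a median of 542. The lowest p belonged to TMEM176B (chromosome 7, 150488376 to 150498448), a membrane protein gene of monocytes and dendritic cells, with 15.9 ± 23.5 FPKM (SD, n = 7) at 6 months and 64.2 ± 91.0 (n = 7) before. Its log2 change was -1.91 ± 0.32, lower in 7 of 7 patients, and did not pass. Replicate 2 had 268.1 FPKM of TMEM176B before treatment and 68.11 at 6 months. The other replicates had 2.871 to 49.98 and 1.3 to 13.61. RPL39L changed by -1.15 ± 0.29, MOB3C by 0.71 ± 0.19 and GPR183, an oxysterol receptor that guides B cells, by 1.63 ± 0.36 (adjusted p = 0.965 for each). Camera called 16 of 33 lists, 7 higher and 9 lower, against 0 with an estimated correlation and 0 with fry. The 2 comparisons with pre-treatment share its libraries. Their log2 changes correlated with r = 0.614 across genes, which are not independent replicates, where simulated data with no change gave a mean of 0.474 (0.447 to 0.492 over 20 simulations). The covariance was 0.0639 (simulated 0.0444), and with disjoint sets of 3 patients it averaged -0.00418 (-0.0745 to 0.0634 over 20 choices), with a mean r of 0.0011 (-0.239 to 0.339). At an unadjusted p under 0.05, 90 genes were lower in both, where simulation gave 56.6 and independent lists would give 4.1, and 55 were higher in both (simulated 55.4, independent 7.78). Genes that move together can spread such values more widely than simulated genes that do not. No excess over chance is therefore read from them. GPR183 was called without replicate 6 (adjusted p = 0.0353), and 661 genes had an unadjusted p under 0.05 without replicate 5. Without replicate 3 and without replicate 4 camera called 10 lists each, and the exact test of the interferon-stimulated list did not pass without replicate 2 (p = 0.0938), nor without any of replicates 1, 3, 4, 5 and 7.

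Genes of inflammatory cytokines and NF-kB targets were higher 6 months after treatment than at its end. Of 30 measured members, 21 rose, adjusted over the list alone, and 28 were above 0. The level was higher by 1.99 ± 1.29 (SD, n = 6 patients) in 5 of 6 patients (exact permutation p = 0.0625). At 6 months levels lay between 2.23 and 6.00 (4.52 ± 1.48, n = 7), and at the end of treatment between 2.63 and 3.34 (2.91 ± 0.30, n = 6). CCL3 rose from 4.18 ± 1.73 to 538 ± 562 FPKM, but its log2 change of 5.57 ± 0.96, higher in 6 of 6 patients, passed only adjusted over the list alone, and over all genes its adjusted p = 0.065.

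CCL3L1 (chromosome 17, 34623842 to 34625730), a chemokine gene nearly identical to CCL3, was the 1 gene called by limma over all genes (adjusted p = 0.0447). It was chosen after its values were seen, as were FFAR2 and IFIT2 where they are the 1 member of a list that passed. It had 336 ± 333 FPKM (n = 7) at 6 months and 2.17 ± 5.11 (n = 6) at the end of treatment, a log2 change of 6.51 ± 1.01, higher in 6 of 6 patients. Its FPKM is the sum of 2 entries with values above 0, and the coordinates are those of 1 of them. At the end of treatment it was 0.05203 to 0.1149 outside replicate 1 (12.61). The size of its change is thus uncertain, with 5.88 to 8.46 over the alternatives. Its copy number differs between people and its reads can be shared with CCL3 and CCL3L3, so that its level is less certain than that of other genes. IL1RN, the antagonist of the interleukin-1 receptor, changed by 3.14 ± 0.55 (adjusted p = 0.065, higher in 6 of 6), IL6 by 3.84 ± 0.77 (adjusted p = 0.143, higher in 5 of 6) and TNF by 3.19 ± 0.79 (adjusted p = 0.351, higher in 6 of 6). Camera called the list with an adjusted p = 1.12e-51, and this was the 1 call in the 3 comparisons that held with an estimated correlation (adjusted p = 0.027). That call was lost without pre-treatment replicate 2 (adjusted p = 0.0979 with an estimated correlation). It was also lost under further alternatives given below, among them no filter, quantile normalization, library weights and the GC correction.

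**Figure D3:**
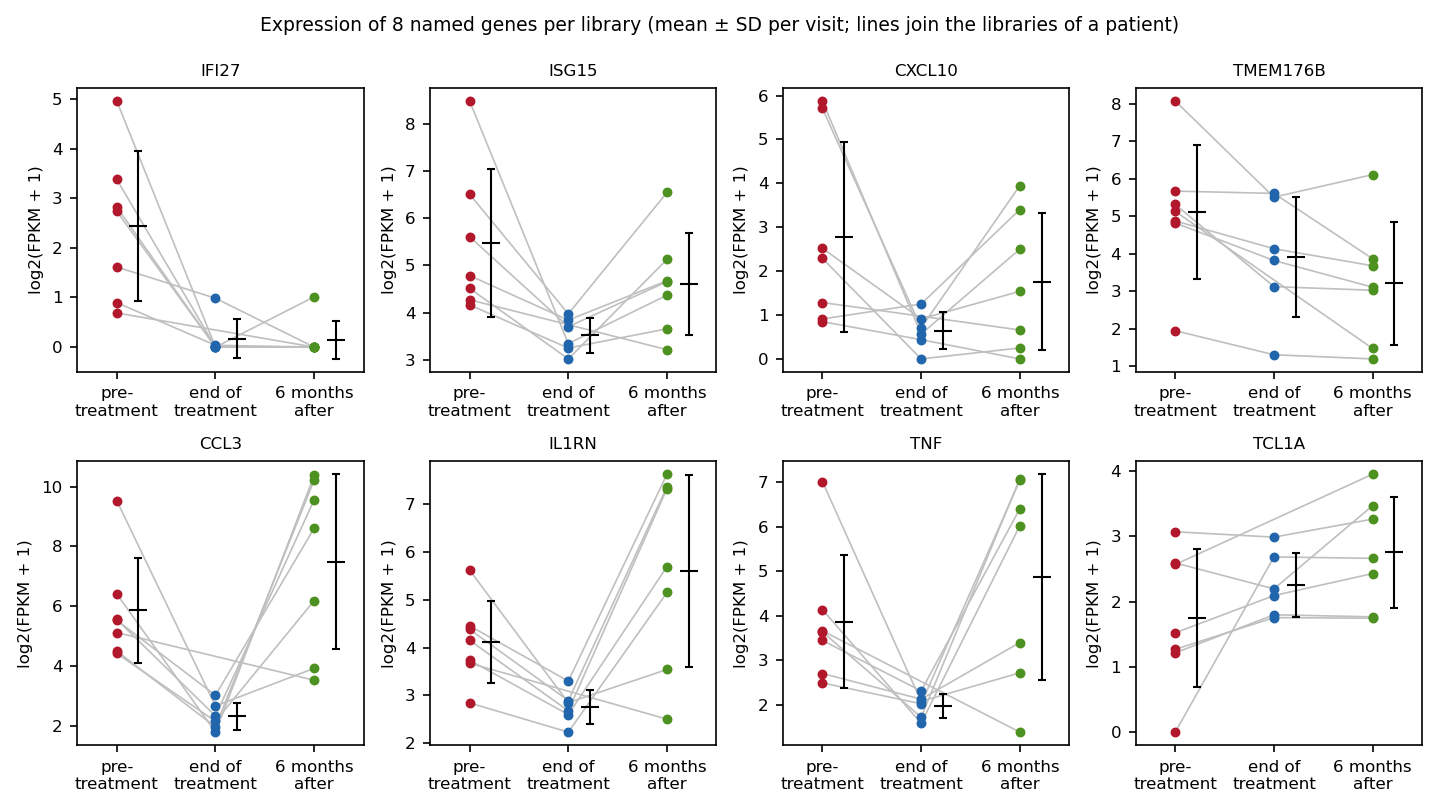
Each panel gives log2(FPKM + 1) of 1 named gene (y axis) at the 3 visits (x axis). Dots are libraries, grey lines join libraries of the same patient, and black marks are the mean ± SD of the log2 values. CCL3 spans 2.43 to 7.07 FPKM at the end of treatment and 10.5 to 1327 at 6 months.

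Immediate early genes rose by camera (adjusted p = 3.76e-12, and adjusted p = 0.117 with an estimated correlation). Of 26 members 2 rose, adjusted over the list alone, which were KLF6, a zinc finger transcription factor (1.06 ± 0.22), and PPP1R15A, a phosphatase subunit induced by stress (2.07 ± 0.48), both higher in 6 of 6 patients. ZFP36, which destabilises cytokine mRNA, changed by 0.83 ± 0.28, while FOS changed by -0.68 ± 0.62 (-0.20 without replicate 1). Neutrophil granule genes, which immature neutrophils express, rose by camera (16 of 17 above 0, 0 adjusted over the list alone, adjusted p = 4.62e-11, and adjusted p = 0.117 with an estimated correlation). LTF, LCN2 and CEACAM8 changed by 1.37 ± 0.48, 1.27 ± 0.46 (0.82 without replicate 6) and 0.88 ± 0.31, and by 2.09, 2.37 and 2.17 with a pseudocount of 0.1, which moved the level difference of the list from 0.58 to 1.01. Mature neutrophil markers rose by camera (adjusted p = 9.84e-07, and adjusted p = 0.417 with an estimated correlation), and of 15 members 1, FFAR2, a receptor for short-chain fatty acids, rose, adjusted over the list alone (2.34 ± 0.51). CXCR2, ALPL and FCGR3B changed by 0.82 ± 0.43, 0.65 ± 0.32 and 0.97 ± 0.61, the last 2 by 0.39 and 0.61 without replicate 5.

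The interferon-gamma response list rose by camera (adjusted p = 4.63e-11, and adjusted p = 0.417 with an estimated correlation). All 26 members were above 0, 0 passed adjusted over the list alone, and the level was higher by 0.54 ± 0.80 in 6 of 6 patients (exact permutation p = 0.0312), with 0.22 without replicate 5. This test did not pass with a pseudocount of 0.1, quantile normalization, median-of-ratios scaling or the GC correction (exact permutation p = 0.0625 for each), and adjusted over the 33 lists no exact test passed in this comparison (smallest adjusted p = 0.458). The list level hardly differed between the visits in replicate 1 (3.1448 and 3.1602) and replicate 6 (3.175 and 3.1778). ICAM1, an adhesion molecule, changed by 1.51 ± 0.52, ATF3, a stress-induced transcription factor, by 1.43 ± 0.49 and CXCL10 by 1.33 ± 0.60. The interferon-stimulated list rose by camera (1 of 35, IFIT2 at 2.54, adjusted over the list alone, adjusted p = 5.92e-06, and adjusted p = 0.477 with an estimated correlation), while IFI44L changed by 0.13 ± 0.40. Erythroid markers rose by camera (0 of 13 adjusted over the list alone, adjusted p = 9.84e-07, and adjusted p = 0.172 with an estimated correlation) and their level was higher by 0.45 ± 0.29 in 6 of 6 patients (exact permutation p = 0.0312). HBB, HBA1 and AHSP, the chaperone of alpha globin, changed by 1.23 ± 0.47, 0.95 ± 0.55 and 0.85 ± 0.40. Classical monocyte markers, by contrast, were at -0.0012 ± 0.40 (SD, n = 6) and were not called (camera adjusted p = 0.812). Markers of B cells (0.543) and T cells (0.557) were not called either, and CD14, MS4A1, CD3E, NKG7 and PPBP changed by 0.12, -0.38, 0.10, 0.31 and 0.40.

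In the comparison of 6 months with the end of treatment, limma called 1 gene. An unadjusted p under 0.05 was found for 234 genes, 158 higher and 76 lower. Although 0.05 of the tested genes is 546, splits that swapped the 2 visits within patients gave a median of only 113. GPR84, a receptor for medium-chain fatty acids on myeloid cells, changed by 1.81 ± 0.35 (adjusted p = 0.143, and 3.61 with a pseudocount of 0.1), and the genes with the lowest p that were lower were FAM206A (-0.97 ± 0.30), HBEGF (-1.56 ± 0.52) and PON2 (-0.79 ± 0.27), which did not pass. Camera called 18 of 33 lists, all higher, against 1 with an estimated correlation and 0 with fry (smallest adjusted p = 0.229). An F test over the 3 visits called 0 genes (429 at an unadjusted p under 0.05, smallest adjusted p = 0.126). The call of CCL3L1 was lost without the replicate block (adjusted p = 0.391), without pre-treatment replicate 2 (0.161) and without replicates 1 (0.192), 2 (0.725), 3 (0.502), 4 (0.0535) and 5 (0.241), over a range of 0.00317 to 0.985 across all alternatives. Without replicate 6, the patient in whom the cytokine level was not higher, 20 genes were called, and with only the 2 visits compared 3 were called.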

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

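The tests of the interferon genes at the end of treatment, of monocyte share in the first 2 patterns, of activation around collection, and of the depth of pre-treatment replicate 2 were chosen after the result was seen, and the remaining tests before. Where a test has an SE, a bound had to be passed by 1 SE in the tests chosen before, and 2 SE were asked of the monocyte tests and of the depth test at the end of treatment, chosen after. A library was singled out where its gap to the nearest library of its visit, relative to the range of the visit, was above Dixon's 95% critical value. Chance does so in about 1 in 20 groups, which is 16 of the 321 groups tested, and 30 were found. Named genes gave 19 of 204 (10 by chance), list levels 5 of 99 (5 by chance) and measures of the libraries 6 of 18 (1 by chance), and 10 of the 30 lay in pre-treatment replicate 2.

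The mean level of the interferon-stimulated list was lower at both later visits than before treatment, by -0.936 ± 0.382 (SE, log2, n = 6 patients) at the end of treatment and -0.57 ± 0.26 (n = 7) at 6 months. At 6 months 1 of 35 members passed adjusted over the list alone, and the camera call was lost with an estimated correlation (adjusted p = 0.335). Lower depth of the pre-treatment libraries would shrink the fall among members of high expression to less than 0.5 of that of the list. These members differed by -1.06 ± 0.422 and -0.588 ± 0.304, beyond that bound by -0.597 ± 0.232 and -0.302 ± 0.174 (SE within patients). This test cannot decide on depth, since these members were chosen by mean FPKM over all libraries, the raised pre-treatment ones included. Adding 1 to FPKM also damps changes of the low members, so that lower depth stays open. A lower share of monocytes is argued against at the end of treatment by a difference minus that of classical monocyte markers of -0.786 ± 0.277, below 0 in 5 of 6 patients, but stays open at 6 months, where it was below 0 in 6 of 7 patients and averaged -0.445 ± 0.278, under 2 SE from 0. A single library stays open as part of it at both visits, since without replicate 4 the difference was -0.706 ± 0.373 and -0.402 ± 0.24, beyond 0.5 of the full difference by -0.238 ± 0.256 and -0.116 ± 0.171, less than the SE within patients. A response to the infection that ended with treatment, which the visits name, may account for the pattern as well and was not tested. It cannot be told apart from lower depth, nor at 6 months from a lower share of monocytes.

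Inflammatory cytokine genes were higher at 6 months than at the end of treatment in 5 of 6 patients. A higher share of monocytes is argued against, since the cytokine difference minus that of classical monocyte markers was 1.99 ± 0.618 (SE) and above 0 in 5 of 6 patients, and GC content of the genes is argued against by a difference of 2.02 ± 0.537 after correction for it. Activation of cells around collection or processing stays open. The pre-treatment library with the highest level (replicate 3) did not share the profile across the 30 members (r = -0.391, rho = -0.429, across genes, which are not independent), which by the bound set at first would have counted against it, but pre-treatment replicate 6 did (r = 0.867, the others -0.568 to 0.11), and since 1 library cannot exclude activation in others the reading of this test was changed after its value was seen. The labels give no collection or processing batch, so that such activation cannot be told apart from a difference between visits, and a candidate explanation of either kind remains a hypothesis.

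Pre-treatment replicate 2 had a median Spearman correlation of 0.6685 with the other libraries (others of its visit 0.856 to 0.899), 8572 genes with at least 1 FPKM (10281 to 10901), 9.58% of FPKM in its top gene (1.46 to 3.24) and 29.44% in its top 10 genes (12.3 to 16.8). Low precision alone is argued against, since pre-treatment replicate 4, with as low an effective fragment number, had a correlation higher by 0.202. That number is not a depth, so that lower depth itself stays open. GC content bias alone is argued against, since its deviation correlated with GC content at rho = 0.489, within the range of the other libraries (-0.534 to 0.54), and end-of-treatment replicate 3, at 0.54, had a correlation of 0.89 with the others, and after correction replicate 2 stood at 0.721 against 0.868 or more. Transcript length bias is argued against by rho = -0.0747 (others -0.126 to 0.146). RNA quality was not tested and the larger share held by a few genes stays open as a part of it, and no biological explanation was tested.

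Other values of pre-treatment replicate 2 that stood apart were low FPKM of JUN (2.87), PON2 (0.05169), NAP1L5 (listed at 0), NDUFB6 (listed at 0) and XCL1 (listed at 0), and a high FPKM of NDUFA11 (89.79, others 12.2 to 21.3). In pre-treatment replicate 6, CCL3 was 739.6 FPKM (others 20.3 to 83.8) and TNF 127.7 (4.64 to 16.6). In pre-treatment replicates 5 and 7, ICAM1 was 4.535 FPKM (others 26.7 to 81.8) and COX7B 73.26 (98.5 to 115). At the end of treatment, CCL3L1 was 12.61 FPKM in replicate 1 (others 0.052 to 0.115), IRF7 6.156 in replicate 5 (2.15 to 3.25) and IFI27 0.9776 in replicate 6 (0 to 0.0255). List levels at that visit stood apart for T cell markers in replicate 6 (4.745, others 5.14 to 5.30) and plasmacytoid dendritic cell markers in replicate 5 (2.814, others 1.66 to 2.06). At 6 months, ATP5G1 was 0.168 FPKM in replicate 3 (others 5.52 to 14.3), S1PR5 63.84 in replicate 4 (12.5 to 23.7), GBP1 88.57 in replicate 5 (6.15 to 16.8), IFI27 1.018 in replicate 2 (listed at 0 in the others), and in replicate 7 JUN was 14.19 (42.0 to 84.7) and HIST2H2AA4 2.367 (12.7 to 34.6). List levels at 6 months stood apart in replicate 5 for the interferon-gamma response (5.111, others 3.16 to 3.72) and plasmacytoid dendritic cell markers (1.461, others 1.80 to 2.05), and in replicate 4 for translation initiation factors (5.42, others 5.02 to 5.14). The effective fragment number of 6-month replicate 6 was 2241568 (others 629267 to 1013439), and the summed FPKM of small RNA genes in end-of-treatment replicate 5 was 4400331 (others 5610 to 99589), which are outside the tests.

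Swapping the visits within patients gave other splits of the libraries. For genes at an unadjusted p under 0.05, chance could not be excluded in any comparison. At the end of treatment against pre-treatment 14 of 32 splits gave as many genes (real value 710, median of the others 536, highest other 2305). At 6 months against pre-treatment 45 of 64 did so (357, median 542, highest 2010). At 6 months against the end of treatment 10 of 32 did so (234, median 113, highest 676). For lists called by camera with the preset correlation, chance could not be excluded either, with 12 of 32 splits (15 lists, highest other 24), 22 of 64 (16, highest 22) and 3 of 32 (18, highest 21). For the 1 gene called at 6 months against the end of treatment, the real split alone among 32 gave a called gene (1 of 32, highest other 0). This is the smallest share that 32 splits can give, it is 1 of 7 such counts, and the call was lost in 16 of 23 alternatives. Chance is therefore not excluded for this gene either. At 6 months against pre-treatment a split with swapped visits called 55 genes, where the real split called 0 and the median of the other splits was 0. Calls can thus arise without a difference between visits, and their cause was not tested. In 100 random splits that ignored the pairing, the highest counts at an unadjusted p under 0.05 were 2621, 2734 and 1341, and 1 random split of 6 months and pre-treatment called 705 genes.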

How the results depend on the processing

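Leaving out pre-treatment replicate 2, leaving out pre-treatment replicates 2 and 4, and the GC correction were chosen after the data were seen, and the other alternatives before. Where a value below differs from that of the report the cause was not tested, except that a filter or a left-out patient changes the number of genes or samples. With an estimated correlation, 0, 0 and 1 lists passed in end of treatment minus pre-treatment, 6 months minus pre-treatment and 6 months minus end of treatment (15, 16 and 18 with the preset correlation), and fry called 0, 0 and 0. Genes called in 6 months minus end of treatment (1 in the report) were 0 with a pseudocount of 0.1, no filter, quantile normalization, median-of-ratios scaling, scaling to a common total, no replicate block, patient as a random effect, robust moderation, small RNA genes kept and the GC correction, 3 at a mean FPKM of at least 5 and with only the 2 visits compared, and 16 with library weights. End of treatment minus pre-treatment had 1 called gene with only the 2 visits compared, and the F test 9 with library weights (0 in the report for both). Leaving out 1 patient or library in turn gave 0 to 1 called genes in 6 months minus pre-treatment, 0 to 20 in 6 months minus end of treatment, 0 to 16 in the F test, and 8 to 21, 10 to 20 and 13 to 20 lists. Genes at an unadjusted p under 0.05 in end of treatment minus pre-treatment (710) were 1142 with no filter, 392 at a mean FPKM of at least 5, 1278 with scaling to a common total, 392 without the replicate block, 396 with patient as a random effect, 354 without pre-treatment replicates 2 and 4, and 381 to 1302 leaving out 1 at a time, and 9 lists passed at a mean FPKM of at least 5. In 6 months minus pre-treatment (357) they were 712 with no filter, 184 at a mean FPKM of at least 5, 157 without pre-treatment replicates 2 and 4, and 247 to 661 leaving out 1 at a time. In 6 months minus end of treatment (234) they were 542 with no filter, 120 at a mean FPKM of at least 5, 459 with only the 2 visits compared, 805 with library weights, 375 without pre-treatment replicates 2 and 4, and 149 to 354 leaving out 1 at a time. The changes of direction were all among genes that did not pass in the report. In end of treatment minus pre-treatment, quantile normalization gave 0.0887 for CD14 and 0.158 for NKG7, scaling to a common total 0.0859 and 0.0674, median-of-ratios scaling -0.0454 and the GC correction -0.126 for PPBP, and library weights -0.0301 for CD3E. Without pre-treatment replicates 2 and 4 they were 0.0623 for CD14, -0.233 for CD3E and 0.0592 for NKG7. In 6 months minus pre-treatment, FCGR3B was 0.0941 with a pseudocount of 0.1, quantile normalization gave 0.0956 for CD14 and 0.0993 for FCGR3B, scaling to a common total 0.0565 and 0.124, and median-of-ratios scaling -0.113 for FOS. Library weights gave -0.0749 for PPBP and -0.574 for FOS, and leaving out pre-treatment replicates 2 and 4 gave 0.168 for CD14, -0.0991 for CD3E and 0.364 for FCGR3B. In 6 months minus end of treatment, quantile normalization gave -0.172 for CD3E, scaling to a common total -0.0294 for CD14 and -0.0529 for CD3E, and library weights -0.0771 for CD14 and -0.0769 for PPBP. Leaving out 1 at a time, end of treatment minus pre-treatment spanned -0.51 to 0.0432 for CD14, -0.11 to 0.51 for CD3E, -0.45 to 0.12 for NKG7 and -0.36 to 0.50 for PPBP. In 6 months minus pre-treatment the spans were -0.42 to 0.23 for CD14, -0.0299 to 0.64 for CD3E, -0.46 to 0.41 for FCGR3B, -0.58 to 0.12 for HBB, -0.0222 to 0.89 for PPBP, 0.0623 to 0.35 for NKG7 and -0.69 to 0.46 for FOS. In 6 months minus end of treatment they were -0.0256 to 0.29 for CD3E, -0.0781 to 0.68 for PPBP, -0.0272 to 0.40 for IFI44L, 0.0055 to 0.23 for CD14, -0.59 to -0.21 for MS4A1 and 0.16 to 0.59 for NKG7. The camera calls of both interferon lists, erythroid markers and the cytokine list in end of treatment minus pre-treatment, of interferon lists, B cell, NK cell and erythroid markers in 6 months minus pre-treatment, and of the cytokine list in 6 months minus end of treatment held with the preset correlation under every alternative in which they were run. The call of the cytokine list with an estimated correlation (adjusted p = 0.027) was lost with no filter (0.163), quantile normalization (0.0709), only the 2 visits compared (0.158), library weights (0.358), the GC correction (0.0859), and without replicates 1 to 5 (0.0507 to 0.238) or pre-treatment replicates 2 and 4 (0.129). Total scaling moved the median log2 change of all genes in 6 months minus end of treatment from -0.03 to -0.18. The F test with only the 2 visits compared and list tests with patient as a random effect were not run, and ignoring the quantification status changed nothing, since every entry is OK. With 5 patients the exact test cannot go below 0.0625, so that leaving out a patient says nothing about its calls in comparisons with the end of treatment. Values of single genes at low FPKM were larger with a pseudocount of 0.1. In end of treatment minus pre-treatment these were TNFAIP6 (-3.43), SELENBP1 (-2.07), TK1 (-1.84), UBE2C (-2.12), RRM2 (-1.28), ZNF383 (1.72) and NAP1L5 (1.74). They were RPL39L (-2.30), TCL1A (1.60), SELENBP1 (-1.98), NDUFB6 (1.36) and XCL1 (1.29) in 6 months minus pre-treatment, and in 6 months minus end of treatment FAM206A (-1.56), PON2 (-1.51), AHSP (1.73) and ALPL (1.64). Library weights gave 0.72 for XCL2, 0.38 for S1PR5, 0.28 for MS4A1, 0.54 for NDUFB6 and -0.757 for HBA1 in 6 months minus pre-treatment, 0.25 for ALPL, 0.49 for CXCR2, 0.35 for FCGR3B and -1.09 for FOS in 6 months minus end of treatment, and 0.63 for MS4A1 in end of treatment minus pre-treatment. Without the replicate block HBA1 was 0.53 and MS4A1 -0.0908 in 6 months minus end of treatment, and quantile normalization gave -0.30 for COX7B in end of treatment minus pre-treatment. Depth is unknown.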

Other observations

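The lists and tests here were fixed before the data were examined, except the values without pre-treatment replicate 2, which were added after the data were seen. At the end of treatment against pre-treatment, innate receptors and inflammasome genes, which sense microbes, fell by camera (0 of 25 adjusted over the list alone, adjusted p = 4.96e-06, and adjusted p = 0.417 with an estimated correlation), as did complement genes (2 of 14, C1QA at -1.85 and C1QB at -1.90, chosen after their values were seen, fell, adjusted over the list alone, adjusted p = 0.0107, and adjusted p = 0.417 with an estimated correlation), a call lost with quantile normalization (adjusted p = 0.0958). Replication-dependent histones, made in S phase, fell by camera (0 of 16, adjusted p = 0.00474, and adjusted p = 0.359 with an estimated correlation). Class II antigen presentation (0.0267), glycolysis (0.0333) and the unfolded protein response (0.0404) were called lower by camera, with adjusted p = 0.417, 0.417 and 0.585 with an estimated correlation, and each of these 3 calls was lost with quantile normalization (adjusted p = 0.536, 0.813 and 0.702). Not called were non-classical monocyte (adjusted p = 0.0505), CD8 T cell (0.108), conventional dendritic cell (0.117), plasmablast (0.344), plasmacytoid dendritic cell (0.881), naive and central memory T cell (0.881) and basophil and mast cell markers (0.881). Heat shock proteins (0.0895), translation initiation factors (0.0958), immediate early genes (0.1), glucocorticoid-induced genes (0.312), cytosolic ribosomal proteins (0.35), p53 targets (0.815) and T cell activation and checkpoint genes (0.935) were not called either. Camera's direction is relative to the other genes, and it was downward where the mean and median were above 0 for cytosolic ribosomal proteins (0.04 and 0.05), p53 targets (0.06 and 0.05) and plasmacytoid dendritic cell markers (0.09 and 0.09), while for classical monocyte markers and translation initiation factors the median was 0.01 and 0.02 and the mean -0.14 and -0.01.

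At 6 months against pre-treatment, camera also called CD8 T cell markers higher (7 of 9 members above 0, adjusted p = 0.0112, and adjusted p = 0.566 with an estimated correlation) and T cell markers higher (13 of 13 above 0, adjusted p = 0.0171, and adjusted p = 0.696 with an estimated correlation). Their levels were higher by 0.30 ± 0.59 (SD, n = 7) in 4 patients and 0.36 ± 1.15 in 5, less than the spread between patients, and without pre-treatment replicate 2 by 0.19 and 0.04. Cell cycle genes were called lower (adjusted p = 0.000257, and adjusted p = 0.566 with an estimated correlation), a call lost without replicate 3 (0.0512) and at a mean FPKM of at least 5 (0.402). Cytosolic ribosomal proteins were called higher (0.0112, lost with median-of-ratios scaling at 0.0973), and innate receptors (0.0174), complement (0.0397), the unfolded protein response (0.0424) and classical monocyte markers (0.0491) lower, and these 4 calls were lost with quantile normalization (0.105, 0.302, 0.289 and 0.632). For these 5 lists the adjusted p with an estimated correlation was 0.696 to 0.833. The mean was above 0 where camera pointed downward for translation initiation factors, class II antigen presentation, glycolysis, platelet markers and heat shock proteins (adjusted p = 0.387 to 0.957, not called), with a median below 0 for class II antigen presentation and glycolysis.

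At 6 months against the end of treatment, camera also called replication-dependent histones higher (15 of 16 above 0, adjusted p = 5.92e-06, and adjusted p = 0.117 with an estimated correlation), with a level higher by 0.49 ± 0.55 (SD, n = 6) in 5 of 6 patients (exact permutation p = 0.0938). Innate receptors (0.000439), NK cell markers (0.00133), cell cycle genes (0.00267, lost at a mean FPKM of at least 5 at 0.201) and platelet markers (0.019) were called higher, with adjusted p = 0.504, 0.473, 0.504 and 0.623 with an estimated correlation. Oxidative phosphorylation (8.46e-05), heat shock proteins (0.017), glycolysis (0.0199), class II antigen presentation (0.0262) and plasmablast markers (0.0478) were called higher, calls that were lost with quantile normalization (0.339, 0.261, 0.54, 0.422 and 0.0687) and with an estimated correlation (adjusted p = 0.417 to 0.588). Cytosolic ribosomal proteins were called higher (9.78e-06, and adjusted p = 0.623 with an estimated correlation), but their direction turned with quantile normalization (0.0687). For CD8 T cell markers (adjusted p = 0.563), naive and central memory T cell markers (0.773) and basophil and mast cell markers (0.94), which were not called, the median and mean differed in sign.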
